A study of Caenorhabditis elegans and Caenorhabditis briggsae and Caenorhabditis remanei with 12 samples.

How the data were processed

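Small RNA was sequenced from whole animals of 4 Caenorhabditis species. C. elegans (strain N2) and C. briggsae (AF16) reproduce as self-fertile hermaphrodites with rare males, while C. remanei (PB4641) and C. brenneri (PB2801) have females and males. Each species gave 1 library of adults, 1 of early embryos and 1 of adult males, which makes 12 libraries. The adult library held hermaphrodites in C. elegans and C. briggsae, and females together with males in C. remanei and C. brenneri. Animals were grown at 20 °C on bacterial lawns. Per the labels' protocols, RNA of 18 to 28 nt was size selected and treated with tobacco acid phosphatase before adapter ligation. That enzyme turns 5′ triphosphates into monophosphates, so secondary siRNAs made by RNA-dependent RNA polymerases could be cloned together with miRNAs and piRNAs. No spike-in was used here, so all values are relative to the reads of the same library.

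The files held, per the file headers, distinct sequences and the number of reads of each. The values are whole-number read counts as deposited by the authors, with no normalization. Each sequence appeared once in its file, every sequence was between 18 and 28 nt, and 0 sequences held a base other than A, C, G or T. The submitters' processing notes name Bowtie; its settings, the genome builds and the filters are not given in the sources used here. The values themselves point to a filter. Of 4011 possible sequences that differ by 1 base from the 5 most read sequences of each library, only 12 were listed. Sequencing errors would have filled that list, so each file appears to hold only sequences that match the reference of its own species without mismatch. A sequence absent from a draft assembly would therefore be absent from the file. The length and quality of the 4 assemblies may differ, and so may the reads lost to this filter.

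Total counts ranged from 4207229 reads in C. elegans adult males to 25386959 in C. elegans adult hermaphrodites. Shares are given with exact Clopper-Pearson 95% intervals in the underlying results, and a count of 0 allows up to 3 reads. Reads carry no molecular identifiers, so intervals and floors cover counting error only. With 1 library per species and stage there is no replication within a species, and no label says how many cultures entered a library. The 4 species were the only replicates of a stage, so the p-values ask whether a stage difference was shared over species.

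Reads were sorted into 4 classes fixed before the data were examined. The class 22G held reads of 22 nt with a 5′ G, 26G held reads of 26 nt with a 5′ G, and 21U held reads of 21 nt with a 5′ U that matched no listed miRNA. A read was given to a miRNA when its first 18 nt were identical to a mature C. elegans miRNA. The 90 mature sequences were written down from memory, not taken from a database, before the data were examined. An error in a sequence would lower the number of miRNAs found. mir-81 and mir-82, which share their first 18 nt, were counted as 1, which left 89. The gene of each of the 90 miRNAs was present in the C. elegans annotation (WBcel235, Ensembl release 115), the mature length was within 1 nt of an annotated one for 89, and 89 of the 90 had at least 10 reads in the C. elegans libraries. mir-241 was the one off in length and mir-797 the one with fewer reads. These checks do not test the 3′ end of a written sequence. At full length, 83 of the 89 had at least 10 reads in C. elegans. mir-71 had 0 full-length reads in all 12 libraries, against 64129 C. elegans reads by its first 18 nt. For mir-247 it was 0 against 419. Their written 3′ ends may be wrong, which would lower counts by full-length identity only. No genome sequence was used. Coordinates are those of the annotated genes in WBcel235, 1-based. let-7 alone was placed by the position of the gene of that symbol in RefSeq. The planned gene-level comparison of antisense 22G reads in C. elegans was not run, because it needs the genome sequence, and the gene lists prepared for it were not used.

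The stage effect on each class share was tested by an exact permutation test. The 3 stage labels were permuted within each species (1296 arrangements), the statistic was the variance of the stage means of the log2 share, and p-values were adjusted over the 4 classes by the Benjamini-Hochberg method. The smallest p this design can give is 0.00463. A sign-flip test of 1 pair of stages over 4 species cannot go below 0.125, so pairs of stages are given as values. All tests were two-sided. Shares were simulated with a noise SD of 0.5 on the log2 scale, 300 times for each setting. The test gave p under 0.05 in 2.67% of simulations without a shift and in 96.0% with a log2 shift of 2. Smaller shifts and wider noise were not simulated. The observed mean log2 difference of embryos to adults was 0.39 for 22G and -1.82 for listed miRNAs. The power of the test at such differences is therefore not known.

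miRNA counts were compared with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, robust). TMM scaling over the miRNAs, species and stage as additive terms, all 12 libraries in 1 fit, and a Benjamini-Hochberg adjusted p under 0.05 defined a call. The 38 miRNAs with at least 10 reads in each of the 4 species were tested. Standard errors (SE) of log2 fold changes were derived from the quasi-likelihood F statistic. With counts simulated for these 38 miRNAs, of which 12 were changed, the procedure recovered 98.3% of 4-fold and 43.1% of 2-fold changes in the embryo comparison, with 2.60% and 1.83% false calls. In the male comparison it recovered 99.2% and 48.3%. All simulated miRNAs shared 1 dispersion (0.113), and a stage change was the same in every species. In the real embryo comparison 30 of 38 were called, far more than the 12 changed in the simulation. These rates therefore may not carry over to the real data. The pairing by species was part of the design. The deviations of libraries from their stage means correlated within each species, with the lowest r at 0.275, over 38 miRNAs. Alternatives were DESeq2 1.42.0, RLE scaling, all reads as library size, no filter, full-length identity, no species term, only the compared stages, and each species left out in turn. Added after seeing the data were a stricter read minimum, counting by seed family, and 2 stricter definitions of 26G and 21U. A seed family comprised reads of 21 to 24 nt, not starting with G, that carried nt 2 to 8 of a listed miRNA. It also collects some reads of other small RNAs.

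Sharing between species was the percent of distinct sequences of a class, with at least 2 reads in the species, that were also read in another species. Named miRNAs were chosen by a fixed rule. It took the 10 largest fold changes in each direction among calls that moved the same way in 4 species, members of fixed miRNA families, and the 3 most abundant listed miRNAs of each library. For the families spelled out in that rule, every tested member was followed through each alternative that tested it, so that none was picked by its stability. That step was added after seeing the data. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 were used for all other steps.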

Results

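The 12 libraries, 1 for each species and stage, differed in depth. C. elegans adult hermaphrodites, embryos and adult males gave 25386959, 9256137 and 4207229 reads, and the same stages of C. briggsae gave 21568112, 14037744 and 4803972. C. remanei gave 19912578 reads from adult females and males, 15451636 from embryos and 5944062 from adult males. C. brenneri gave 18266517, 16214503 and 8285220. The submitters' title names miRNAs, piRNAs and siRNAs in 4 species, and the labels vary species, stage and sex. In all 12 libraries the most frequent length was 22 nt, from 35.6% of reads in C. remanei males to 57.2% in C. elegans embryos, and G was the most frequent first base of these reads. Each stage was represented by 4 libraries, 1 per species, and no library had a replicate of its own kind. Values given as mean ± SD are over the 4 species.

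The first question was how the siRNA and piRNA classes differed between adults, embryos and males. Reads of 22 nt with a 5′ G, the form of secondary siRNAs that act with worm-specific Argonautes, made up 23.9% ± 4.26 (SD, n = 4) of reads in adults, 31.03% ± 1.77 in embryos and 22.7% ± 1.90 in males. The embryo share was above the adult share in 4 of 4 species. The shares were 29.051% and 29.004% in C. elegans, while the ratio was 1.60 in C. briggsae, 1.28 in C. remanei and 1.45 in C. brenneri. Embryos were also above males in 4 of 4 species. The exact permutation test over stages gave p = 0.0509 (adjusted p = 0.0802, n = 4 species), so the stage difference did not pass. The 95% interval of the C. elegans adult share was 28.99% to 29.02%, which shows that counting error was small beside the spread between species.

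Reads of 21 nt with a 5′ U outside the listed miRNAs, the form of Caenorhabditis piRNAs, were 12.8% ± 7.67 (SD, n = 4) of reads in adults, 6.96% ± 2.66 in embryos and 8.49% ± 4.67 in males. Embryos and males were each below adults in 4 of 4 species. The ratio of embryo to adult was 0.764 in C. elegans, 0.708 in C. briggsae, 0.624 in C. remanei and 0.378 in C. brenneri. For males the same ratio was 0.971, 0.870, 0.415 and 0.698. The exact permutation test over stages gave p = 0.0602 (adjusted p = 0.0802, n = 4), and without C. remanei the exact permutation p was 0.0278, the smallest that 3 species allow. The C. remanei male library, which gave the lowest male ratio, differed from its adult library in other ways too. It held 5.48% of reads at 18 nt against 0.420%. One group of nested sequences, described further below, supplied 8.38% of its reads against 0.0315%. Reads of that group outside the 21U class lower the 21U share of the male library. Its 21U reads were 2.47 times as frequent at 21 nt as at the mean of 20 and 22 nt, against 11.9 times. The ratio was lower still in embryos of C. briggsae (1.18) and C. brenneri (2.26). Reads of unlisted miRNAs with a 5′ U also enter this ratio, in its 20 and 22 nt part too. Reads with the mir-35 seed, most of them unlisted, made up 8.86% and 6.59% of those embryo libraries. In C. remanei males they were 0.0144%. The embryo values therefore cannot show whether a weak 21 nt peak is particular to C. remanei males. Degraded RNA in the C. remanei male library was not tested. Species lay further apart than stages. The mean share over the 3 stages was 4.74% in C. elegans, 6.84% in C. briggsae, 10.8% in C. remanei and 15.3% in C. brenneri. An exact permutation of species labels within stages, added after seeing the data, gave p = 0.0104 (adjusted p = 0.0243 over 4 classes). Unlisted miRNAs can enter 21U in the species other than C. elegans. Without sequences of a listed miRNA seed, C. briggsae held 6.24%, 4.67% and 4.27% in adults, embryos and males. C. elegans then held 5.18%, 3.96% and 4.99%, and C. remanei and C. brenneri stayed above both at each stage. The p-values above include these sequences.

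Reads of 26 nt with a 5′ G, the form of primary siRNAs known from the germ line and embryos of C. elegans, were the rarest class. They were 0.860% ± 0.599 (SD, n = 4) of reads in adults, 2.21% ± 2.24 in embryos and 2.12% ± 0.665 in males. Both embryos and males were above adults in 4 of 4 species. Embryos held 2.31-fold more than adults in C. elegans, 2.15-fold in C. briggsae, 1.47-fold in C. remanei and 3.61-fold in C. brenneri. Males held 8.17-fold more than hermaphrodites in C. elegans and 5.98-fold more in C. briggsae. In C. remanei and C. brenneri, where the adult library itself contained males, the ratio was 1.30 and 1.39. The highest share of any library was 5.47% in C. brenneri embryos. The exact permutation test over stages gave p = 0.106 (adjusted p = 0.106, n = 4). One fragment that begins like 5S ribosomal RNA supplied 30.3% of the 26G reads of C. elegans hermaphrodites. Without sequences of that start, a setting chosen after seeing the data, the male ratio was 11.3 in C. elegans, 7.11 in C. briggsae, 1.32 in C. remanei and 1.23 in C. brenneri.

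**Figure D1:**
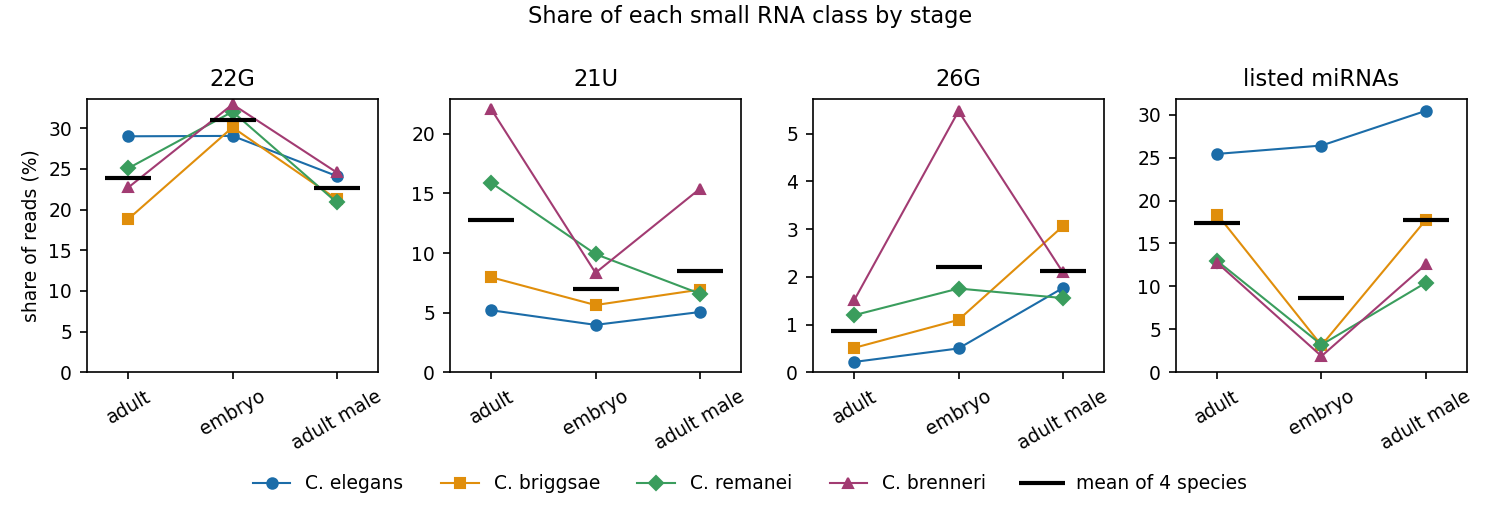
Share of reads in percent (vertical axes, from 0) for 22G, 21U, 26G and listed miRNA reads in adults, embryos and adult males. Each point is 1 library, lines join the libraries of a species, and black bars are means of 4 species. The 22G mean was 31.03% in embryos against 23.9% in adults, and the listed miRNA share of C. elegans embryos, 26.4%, lay apart from the other 3 species.

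Reads of the listed miRNAs made up 17.4% ± 5.97 (SD, n = 4) of reads in adults, 8.65% ± 11.9 in embryos and 17.8% ± 8.98 in males. The list is from C. elegans, which favours that species. In C. elegans the share was 25.4%, 26.4% and 30.4% for hermaphrodites, embryos and males. The embryo share was 3.13% in C. briggsae, 3.20% in C. remanei and 1.87% in C. brenneri, against 18.4%, 12.96% and 12.7% in their adults. The exact permutation test over stages gave p = 0.0602 (adjusted p = 0.0802, n = 4). Without C. elegans the exact permutation p was 0.0278.

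Counted by seed, which also takes in relatives of the listed miRNAs in the other species, 2 opposite patterns stood behind these totals. This count was chosen after seeing the data. The mir-35 seed family, whose members are required for embryonic development in C. elegans, was 1.52% ± 1.70 (SD, n = 4) of reads in adults, 9.40% ± 7.88 in embryos and 0.0534% ± 0.0306 in males. It rose in embryos and fell in males in 4 of 4 species, with log2 differences to adults of 3.13 ± 1.34 and -4.13 ± 1.88 (SD). The exact permutation p was 0.00463, the smallest possible (adjusted p = 0.0139 over 3 measures). The family reached 20.4% of reads in C. elegans embryos, 8.86% in C. briggsae, 1.79% in C. remanei and 6.59% in C. brenneri. All other listed seed families together fell in embryos in 4 of 4 species, from 20.2% ± 4.91 in adults to 4.17% ± 1.80 (exact permutation p = 0.0231, adjusted p = 0.0347).

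**Figure D2:**
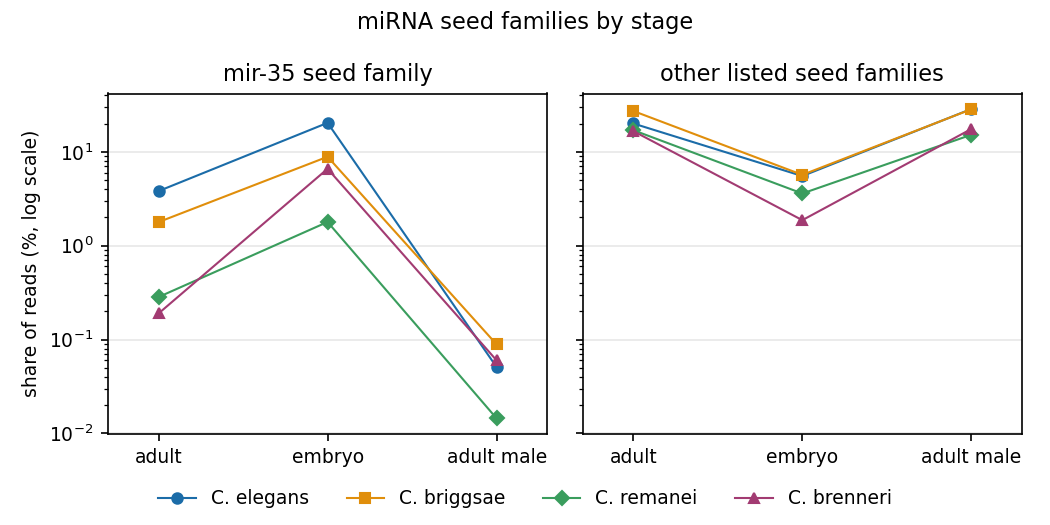
Share of reads in percent (log axis) of the mir-35 seed family and of all other listed seed families, by stage. Each point is 1 library and lines join a species. The mir-35 family peaked in embryos (mean 9.40%) and was at most 0.0886% in males, while the other families were lowest in embryos (mean 4.17%).

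The embryo comparison of single miRNAs asked which of them differed from adults in the same way over species. Of 38 miRNAs tested, edgeR called 30 at an adjusted p under 0.05, 11 higher and 19 lower in embryos, relative to the TMM scale of these miRNAs. The heterochronic miRNAs, which time larval development, were nearly absent from embryos. let-7 (X:14743590-14745321) fell by 7.24 ± 0.45 on the log2 scale (SE, edgeR adjusted p = 4.86e-11), and its family member mir-48 (V:14364412-14364509) fell by 8.77 ± 0.44. lin-4 (II:5902254-5902347) was read 0 times in C. elegans embryos, which allows up to 3.24e-05% of reads, and 1, 2 and 1 times in the embryos of the other species. It had 9610 reads in C. elegans hermaphrodites and fell by 9.18 ± 0.47 in the fit (edgeR adjusted p = 4.17e-12). The size of this fitted change depends on the prior count. mir-77 (II:12519268-12519367) had 8 reads in C. elegans embryos and 216803 in hermaphrodites, and fell by 9.56 ± 0.59 on the log2 scale. mir-34, a regulator of stress responses, fell by 6.73 ± 0.40, and mir-71, which promotes adult longevity, by 5.57 ± 0.55. mir-238 fell by 4.43 ± 0.49, mir-83 fell by 3.64 ± 0.43 and mir-80 fell by 3.03 ± 0.22, and mir-252 was 6.97-fold lower. The muscle miRNA mir-1 fell by 1.76 ± 0.37 and the intestinal mir-60 fell by 1.62 ± 0.34 (edgeR adjusted p = 0.000337 for both). These falls held in 4 of 4 species, also with all reads as library size. Without C. elegans some were smaller, as mir-77 fell by 8.96, lin-4 fell by 8.47, mir-80 fell by 2.41 and mir-1 fell by 1.03 on the log2 scale.

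The 2 largest gains belonged to neighbours on chromosome II of C. elegans. mir-43 (II:11889910-11890007) was 31.1-fold higher in embryos (log2 4.96 ± 0.58, edgeR adjusted p = 5.67e-07). mir-42 (II:11889811-11889905), the only member of the mir-35 family with 18 nt shared by all 4 species, was 18.8-fold higher (log2 4.23 ± 0.84, edgeR adjusted p = 0.00129). mir-44 (II:11890023-11890118) was 2.77-fold higher. Reads were assigned by sequence alone, so a gene off the list with the same first 18 nt would be counted with it. Then came mir-74 (6.09-fold), mir-90 (5.51-fold), the neuronal lsy-6 (4.92-fold), mir-244 (3.90-fold), mir-52 of the mir-51 family (2.02-fold), mir-355 (2.01-fold) and mir-233 (1.66-fold). These gains are relative to the other miRNAs. With all reads as library size the median of the 38 miRNAs moved from -0.53 to -3.38, a shift of -2.85 on the log2 scale, and the split became 1 higher and 32 lower. mir-43 alone stayed a call on the higher side, with log2 1.95 ± 0.45. mir-42 kept its sign, and mir-44, mir-74, mir-90, lsy-6, mir-244, mir-52, mir-355 and mir-233 turned negative. With RLE scaling the split was 16 higher and 16 lower. Of the 3 measured members of the mir-58 family, which TMM scaling split into 1 higher, 1 lower and 1 without a call, all 3 fell with all reads as library size. The neuronal mir-124 was not called (log2 -0.17 ± 0.32, edgeR adjusted p = 0.624), and its sign changed with DESeq2 and RLE scaling. mir-2, in the family of mir-43, depended on scaling. edgeR with TMM did not call it (log2 0.58 ± 0.36, edgeR adjusted p = 0.142), DESeq2 called it higher (log2 1.12, DESeq2 adjusted p = 0.000563), and with all reads as library size it was called lower. lsy-6 rested on few reads, at most 33 in any embryo library, and on C. remanei, without which its log2 was 1.19 (3.13 without C. elegans). Besides the reversal with all reads, the embryo calls of mir-355 and mir-58 were lost in 6 of 12 alternatives, that of mir-233 in 5 of 12, that of mir-52 in 3 of 12 and that of lsy-6 in 2 of 10. The call of mir-42 was lost in 2 of 12, and that of mir-60 on the lower side in 1 of 11. Without C. remanei or C. brenneri the calls of mir-52 (log2 1.07 and 0.91), mir-233 (0.58 and 0.51), mir-355 (0.66 and 1.04) and mir-58 (0.40 and 0.31) were lost. Without C. briggsae those of mir-355 (0.97) and mir-58 (0.42) were lost, and without C. brenneri that of mir-42 (3.82). Without C. briggsae mir-43 rose to log2 5.66 and mir-42 to 4.90, and without C. elegans mir-244 rose to 2.60 and mir-355 to 1.69.

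The male comparison asked the same of adult males against adults. edgeR called 8 of 38 miRNAs, 2 higher and 6 lower, and all 8 moved the same way in 4 of 4 species. mir-90 (III:8873987-8874084), of the mir-50 family, rose 6.36-fold in males (log2 2.67 ± 0.29 SE, edgeR adjusted p = 1.40e-06). Per all reads it was 13.5-fold higher in C. elegans, 3.34-fold in C. briggsae, 3.55-fold in C. remanei and 3.60-fold in C. brenneri. mir-58 (IV:3233254-3233350), a member of one of the most abundant miRNA families of the worm, rose 2.56-fold (log2 1.36 ± 0.17, edgeR adjusted p = 2.71e-06). Both also rose with all reads as library size, by 4.76-fold for mir-90. The other 2 measured features of the mir-58 family did not pass, although mir-80 was lower in 4 of 4 species (edgeR adjusted p = 0.0602) and passed in 6 of 12 alternatives. mir-79 (I:9332946-9333043) fell 5.34-fold (log2 -2.42 ± 0.27, edgeR adjusted p = 1.40e-06), mir-67 (III:5931349-5931447) fell 5.36-fold and mir-83 (IV:7841631-7841728) fell 3.55-fold. mir-67 had few reads, 90 in C. elegans hermaphrodites and 1 in males. Smaller falls were called for mir-77 (2.26-fold), mir-62 (1.90-fold) and mir-34 (1.87-fold). Their edgeR adjusted p lay between 0.0304 and 0.0448. The calls of mir-34 and mir-77 were lost in 5 of 12 alternatives and that of mir-62 in 4 of 12. Those of mir-67 and mir-83 were lost only without the species term. Losses on leaving out a species were those of mir-34 without C. briggsae, C. remanei or C. brenneri (log2 -0.80, -0.80 and -1.08), mir-77 without C. elegans, C. briggsae or C. brenneri (-1.19, -0.85 and -1.41) and mir-62 without C. briggsae or C. brenneri (-0.77 and -1.01). Gains were those of let-7 without C. elegans (0.93) and mir-80 without C. brenneri (-0.72). mir-49, lower in males, was also gained without C. elegans (edgeR adjusted p = 0.0439). let-7 was 1.74-fold higher (edgeR adjusted p = 0.0776) and mir-1 was 1.76-fold lower (edgeR adjusted p = 0.104), and neither passed over all 38, but let-7 passed in 4 and mir-1 in 5 of 12 alternatives. lin-4, which nearly vanished in embryos, was not called in males (1.07-fold, edgeR adjusted p = 0.868). Adjusted over each list alone, 5 lists gained 1 call each: the let-7, mir-35, mir-29 and mir-58 families and the muscle miRNA mir-1. mir-1 and mir-42 of the mir-35 family were each the only tested member of their list. Their edgeR p-values, 0.0327 and 0.0456, were thus unadjusted. No correction was made over the lists, so these gains are weak. The count of calls was 3 without the species term, 17 with only adults and males in the fit, and 5 without C. briggsae. With all reads as library size the median moved from -0.11 to -0.53, a shift of -0.43 on the log2 scale, and 2 were called higher and 10 lower.

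**Figure D3:**
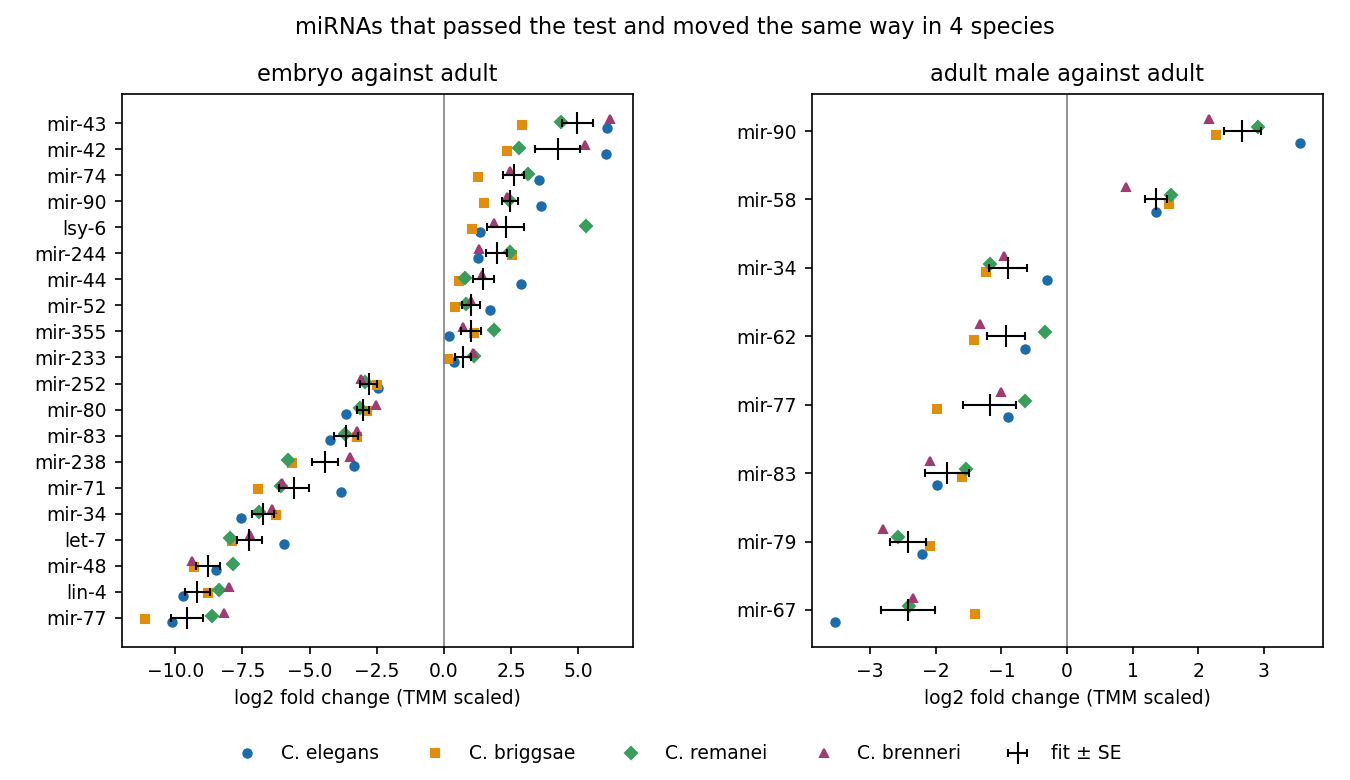
Log2 fold change against adults (horizontal axes, TMM scaled) of the miRNAs named by the fixed rule, for embryos (left) and adult males (right). Coloured points are the 4 species, black bars are the edgeR estimate with its SE. mir-90 rose in males by 2.67 on the log2 scale and lin-4 fell in embryos by 9.18. With all reads as library size, all embryo gains except mir-43 and mir-42 of those shown turned negative.

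The most abundant listed miRNAs were much the same in adults of all 4 species. mir-80, mir-81/mir-82 and mir-58, all of the mir-58 family, held the first 3 ranks in each adult library, with mir-80 at 3.92% of reads in C. elegans and 5.05% in C. briggsae. In males mir-58 was first in 4 of 4 species, at 7.69% of reads in C. elegans and 6.35% in C. briggsae. mir-90 had rank 3 in males of C. remanei and C. brenneri, at 1.63% and 1.93%. C. elegans embryos were led by mir-39 with 12.3% of reads, mir-36 with 3.88% and mir-35 with 2.05%. Embryos of C. remanei were led by mir-40 (0.713%) and those of C. brenneri by mir-38 (0.464%), both of the mir-35 family. Among listed miRNAs, C. briggsae embryos were led by mir-81/mir-82 (0.739%) and mir-58 (0.676%), followed by mir-36. These ranks leave out each species' own relatives of the mir-35 family and of other listed miRNAs. By seed, C. remanei males held 134420 reads of the mir-235 seed, against 96976 of mir-90. C. brenneri males held 188553 reads of the lin-4 seed family, against 159823 of mir-90, while lin-4 itself had 1378. By seed, C. briggsae embryos held 1243828 reads of the mir-35 family against 221825 of the mir-58 family. In C. brenneri an unlisted sequence with 2 mismatches to mir-39 had 449583 reads over all stages, against 81340 for mir-38.

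How far mature miRNA sequences were kept between species was asked by the number found. Of the 89 listed miRNAs, 88 had at least 10 reads in C. elegans, 45 in C. briggsae, 53 in C. remanei and 53 in C. brenneri. In all 4 species 38 were found, and 27 were found only in C. elegans. All 3 features of the mir-58 family, both of the mir-46 family, mir-1, mir-34, mir-60 and mir-71 were among the 38. The mir-64 family had 0 of 5 members in all 4 species, the let-7 family 2 of 7 and the mir-35 family 1 of 8. mir-39, the most read miRNA of C. elegans embryos, had 0 reads in the other 3 species, and mir-72, with 790453 reads in C. elegans, had 0 in C. briggsae.

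The same question for the other classes had a different answer. Of distinct miRNA sequences, 59.2% in C. elegans, 84.4% in C. briggsae, 88.6% in C. remanei and 88.5% in C. brenneri were also read in another species. The listed miRNAs are defined by identity over 18 nt, which raises this share by construction. For 21U it was 0.814% to 2.03%, for 22G 0.903% to 1.44%, and for 26G 0.854% to 2.57%. Counted by reads, 15.8% of C. elegans 26G reads lay in shared sequences, but without sequences of the 5S ribosomal RNA start, a setting chosen after seeing the data, it was 3.02%. Sharing depends on depth, and 1 read in the other species was enough.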

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

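The tests of seed families, mir-90, the length peak and the 10 most read sequences were all chosen only after the results, or values close to them, had been seen.

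The listed miRNA share of C. elegans embryos, 26.4%, lay far from that of the other 3 species, whose embryos held 1.87% to 3.20%. This was the 1 of 12 sets of 4 libraries (4 classes in 3 stages) with a library standing apart. Chance flags about 1 in 20 such sets, so 1 flag among 12 can arise by chance. One explanation is that a C. elegans list misses the other species' own mir-35 relatives. Counting by seed family raised the embryo to adult ratio to at most 0.546 in the other species, against 1.08 in C. elegans. That count was widened to the first 7 nt of mir-35 after a first value of 0.503 in C. brenneri, the species it raised. So this is not the whole cause. A second explanation is the size of the mir-35 family itself in C. elegans embryos. Without reads of the mir-35 seed the C. elegans ratio was 0.275, and the lowest of the other species was 0.112. The data are consistent with a fall of the other seed families, summed, in embryos of all 4 species that mir-35 family reads offset in C. elegans. Single miRNAs outside that family, such as mir-43, did rise. Assembly gaps in the other species stay open as part of the difference.

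The 26G ratio of males to embryos went in opposite directions in the species with hermaphrodites and those with females. It was 3.54 and 2.79 in C. elegans and C. briggsae, and 0.886 and 0.384 in C. remanei and C. brenneri, a difference of 2.43 in mean log2. The difference was not tested, since 4 species fall into 2 pairs in only 3 ways. The gain of males over adults was likewise large in the first pair (8.17 and 5.98) and small in the second (1.30 and 1.39). Males inside the mixed adult libraries are the first candidate explanation, since they would dilute every male-biased RNA alike. But mir-90 was 3.55-fold and 3.60-fold higher in males of C. remanei and C. brenneri per all reads. If reads follow RNA, males can then have supplied at most 28.2% of the adult RNA, and females would still hold 0.679 and 0.614 of the male 26G level, against 0.122 and 0.167 for hermaphrodites. That bound has no interval. It rests on 1 library of each kind and on mir-90, which had the largest called male gain in these same data. Random 26 nt fragments in adults are a poor account too. Adult reads with a 5′ G were 5.31 and 10.5 times as frequent at 26 nt as at the mean of 25 and 27 nt. The peak was weaker in males, at 3.70 and 7.88 times, so fragments may make up a larger part of male 26G reads. Nor did a few sequences set the ratio of males to adults, which was 1.30 and 1.26 without the 10 most read 26G sequences of each library. These tests bear on the gain over adults, where a difference in adult 26G levels between hermaphrodites and females may remain as an untested hypothesis. They do not bear on the ratio to embryos, to which the higher embryo shares of C. remanei and C. brenneri (1.76% and 5.47%, against 0.499% and 1.10%) also contributed and for which no explanation was tested. Age of the animals and library batches were not given by the labels.

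One group of nested sequences that share a single 3′ end of 13 nt, and match no listed miRNA, supplied 8.38% of reads in C. remanei males. It was 0.920% in C. remanei embryos, 0.0315% in C. remanei adults and 0 reads in all libraries of the other 3 species. It spanned 11 lengths.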

How the results depend on the processing

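The stricter read minimum, seed families, and the 26G definitions (stage share and sharing) and 21U definition without 5S starts or miRNA seeds were chosen only after the data were seen; all other alternatives were set out before. The 26G share stayed short of the threshold in all 11 alternatives (exact permutation p 0.0556 to 0.333). As a share of distinct sequences the order of stages changed for 22G (exact permutation p = 0.0370), 21U (exact permutation p = 0.194) and listed miRNAs (exact permutation p = 0.0324). Males were then highest in each, as they already were for listed miRNAs. Embryos stayed above adults for 22G (22.8% against 21.6%). They moved just above adults for 21U (2.19% against 2.18%) and listed miRNAs (0.0114% against 0.0101%). The 22G stage difference passed without sequences read once (exact p = 0.0417), without the 10 most abundant sequences (exact p = 0.0370) and on untransformed shares (exact p = 0.0370). The listed miRNA share passed without the 10 most abundant sequences (exact p = 0.0370). Leaving out 1 species gave exact p from 0.0833 to 0.194 for 22G, and from 0.0278 to 0.222 for 21U and for listed miRNAs. The cause of these moves was not tested.

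The count of 30 embryo calls lay between 22 and 33 in the other alternatives and was 59 with no filter, where 89 miRNAs were tested instead of 38. Leaving out 1 species gave 24 to 30. The 8 male calls became 19 with no filter, 3 without the species block and 17 with only the 2 stages, and 5 to 9 when 1 species was left out. DESeq2 called 33 in embryos, 28 of them shared with edgeR, and 9 in males, all 8 edgeR calls included. With all reads as library size, 14 of 16 embryo gains, called or not, reversed, as did 6 gains in males. Among the miRNAs followed through the alternatives these were, in embryos, mir-74 to -0.28, mir-90 to -0.46, lsy-6 to -0.41, mir-244 to -0.77, mir-44 to -1.49, mir-52 to -1.90, mir-355 to -1.76, mir-233 to -2.13, mir-2 to -2.37, mir-58 to -2.47 and mir-81/mir-82 to -2.53 on the log2 scale. In males they were lin-4 (-0.30), mir-2 (-0.34) and mir-81/mir-82 (-0.10). This scaling, by its construction, counts the fall of miRNAs against all reads. The other reversals among followed miRNAs were of values near 0 that were not called. mir-124 in embryos became 0.36 with DESeq2, 0.36 with RLE scaling and 0.0452 with full-length identity, and ranged from -0.52 to 0.20 when 1 species was left out. In males, no filter gave mir-43 0.13, mir-52 0.24, mir-60 0.0352, mir-74 0.0720 and mir-124 0.12. No species block gave mir-60 0.11 and mir-74 0.0770, full-length identity gave mir-52 0.00829, and at least 100 reads gave lin-4 -0.00700 and mir-2 -0.0187. Leaving out 1 species gave lin-4 -0.12 to 0.22, mir-2 -0.0166 to 0.15, mir-43 -0.53 to 0.39, mir-52 -0.104 to 0.0135 and mir-74 -0.50 to 0.13. No other pairing was possible because the libraries carry no replicate numbers.

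The number of known miRNAs stayed within 1.5 times for each species with 100 reads or full-length identity (34 to 85). The share of sequences found in another species moved beyond its counting interval in 26 of 36 cases. With at least 10 reads it was 1.23% for C. elegans 22G, 3.35% for C. elegans 26G, 3.71%, 1.86% and 2.56% for C. briggsae 21U, 22G and 26G, 0.447% and 1.17% for C. remanei 21U and 22G, and 0.620%, 1.18% and 0.691% for C. brenneri 21U, 22G and 26G. As a share of reads it was 1.29%, 1.10% and 15.8% for C. elegans 21U, 22G and 26G, 95.1%, 0.910%, 2.15% and 8.24% for C. briggsae miRNA, 21U, 22G and 26G, 0.285%, 1.36% and 4.60% for C. remanei 21U, 22G and 26G, and 99.1%, 0.331%, 1.31% and 2.85% for C. brenneri miRNA, 21U, 22G and 26G. Without 5S starts the share of 26G reads was 3.02% in C. elegans and 0.419% in C. brenneri, so fragments with that start made up most of the shared 26G reads. Every miRNA value stayed above every value of the other classes. The planned gene-level 22G comparisons in C. elegans were not run for lack of a genome sequence here. Depth limits the male libraries most, at 4207229 to 8285220 reads.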

Other observations

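The tests of changed miRNA sequences and of other splits of the libraries, and the count by seed family, were chosen only after the results, or values close to them, had been seen. A minority of the 26G sequences of males were read in embryos. Of the 26G sequences with at least 10 reads in C. elegans males, 4.13% were also read in embryos, against 86.5% of 22G and 93.0% of 21U sequences of the same library. The 26G value was 18.5% in C. briggsae, 32.9% in C. remanei and 33.0% in C. brenneri, below 22G and 21U of the same library in each species. By reads it was 10.2%, 22.2%, 38.4% and 52.5% of male 26G reads, with C. elegans first and the others in the order above. In the other direction, 42.6%, 48.7%, 37.2% and 21.8% of embryo 26G sequences (73.7%, 71.0%, 55.6% and 37.8% of their reads) were also read in males. Male 26G sequences were found in the adult library more often, at 79.9%, 44.1%, 95.2% and 98.9% in the same order of species. The adult libraries were deeper than the embryo libraries in all 4 species, and those of C. remanei and C. brenneri contained males, so the adult and embryo values are not on an equal footing.

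Counted by seed family and tested with edgeR, the mir-35 family was 51.5-fold higher in embryos relative to other families (edgeR adjusted p = 3.83e-05) and 12.3-fold lower in males (edgeR adjusted p = 0.00477), over 4 species. The mir-50 family, which holds mir-90, was 5.75-fold higher in males (edgeR adjusted p = 0.000983), and the mir-235 seed 4.21-fold higher (edgeR adjusted p = 0.00105). mir-235 itself had 98933 reads in C. elegans and 0 in the other 3 species by its first 18 nt. No miRNA passed a test of different stage changes between the 2 kinds of species with edgeR (0 of 38 at an adjusted p under 0.05, with 2 in embryos and 1 in males at an unadjusted p under 0.05).

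A listed miRNA with 0 reads in a species may be lost, changed in sequence or missing from the assembly. Of 108 cases with at least 100 reads in C. elegans and under 10 in another species, 68 (63.0%) had a sequence of 21 to 24 nt with the same seed, 1 to 3 mismatches in the first 18 nt and at least 100 reads. With nt 9 to 18 of each miRNA put in reverse order, 0 of 108 had one. mir-235 was an example, with 300088 reads of a sequence with 1 mismatch in C. remanei. The 68 cases rest on 58 sequences, 22 in C. briggsae, 20 in C. remanei and 16 in C. brenneri, since 1 sequence can be the near match of several family members. A changed sequence may thus account for many of these cases, but where relatives share a near match, loss of single members stays open. For the other cases loss and assembly gaps stay open.

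Other splits of the libraries gave fewer miRNA calls in both comparisons. Among the 35 splits of the 8 adult and embryo libraries into 4 and 4, 1 split, the real one, gave 30 calls and the highest of the others gave 0. For adults and males the real split was again the 1 split with 8 calls, and the highest of the others, which set whole species against each other, gave 4. Only 8 of the 35 splits keep the pairing by species, with 1 library of each species on either side. Among these the highest of the others gave 0 in both comparisons, but 8 splits are too few for a share under 0.05. In every other split the real stage difference enters the residual spread, which by itself lowers the calls. The splits therefore cannot show how many calls would arise without a stage difference.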
